A study of Mus musculus with 12 samples.

How the data were processed

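RNA was measured in monocytes that had been sorted from mouse bone marrow and cultured with or without LPS. Per the labels, the animals had received 300 mM succinate for 7 days or none, total RNA was extracted with Trizol, and a sequencing company prepared the libraries by its own protocol. The deposited file of each library gives whole-number read counts per gene, not normalised, which the authors made from reads processed with Trim Galore and the mm10 build, per the submitters' processing notes. The aligner, the counting tool, the annotation, the handling of strand and the tool versions are not given in the sources used here, so how reads of overlapping genes, antisense genes and near-identical copies were assigned is not known here. The 12 files list the same 54532 genes. Of their identifiers, 54409 (99.8%) are in the GENCODE M21 annotation of GRCm38, the assembly behind mm10, which gave the coordinates, exonic lengths and GC contents, and 123 are not. A count above 0 in at least 1 library was found for 28563 genes. Symbols shared by several identifiers (207 entries) were told apart by identifier.

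Groups were taken from the sample titles: 4 groups of 3 libraries. Total counts per library ranged from 15975882 to 18306747. At this depth and spread the median standard error of a log2 fold change between 2 groups was 0.19, and 0.14 for genes with at least 10 CPM. For the interaction it was 0.269 and 0.198. Libraries of 1 group had Pearson correlations of 0.985 to 0.988 across genes and chi-square values per degree of freedom of 6.42 to 38.72, so no 2 libraries held the same counts within sampling noise and each was kept as 1 sample. Y-linked genes had 0 or 1 count and Xist 12551 to 19840 counts in each library.

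Genes were tested with edgeR 4.0.16 (R 4.3.3) on the counts as deposited. Low genes were removed with filterByExpr, which left 14324 genes and removed 14239, keeping at least 99.87% of the counts of each library. Libraries were scaled by trimmed means of M values (TMM), and a quasi-likelihood negative binomial model with 1 mean per group was fitted to all 12 libraries (common biological coefficient of variation 0.167). The 5 contrasts were LPS against none in control mice, the same in succinate mice, succinate against control without LPS, succinate against control with LPS, and the interaction (the difference between the 2 LPS effects). A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over the tested genes. Standard errors come from the quasi-likelihood fit, and 95% intervals use the same standard errors. Log2 CPM values used a prior count of 2. Where a group had no count for a gene, a fold is given as a lower bound from 3 counts over the group, and with 1 to 3 counts as a ratio with an exact 95% counting interval.

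Before the data were examined, 32 gene lists were fixed: inflammatory cytokines and chemokines, interferon-stimulated genes, feedback regulators of inflammation, IL-4 target genes, IL-4 receptor signalling components, HIF-1 target genes, glycolysis, the TCA cycle, the nuclear-encoded respiratory chain, mitochondrially encoded genes, ribosomal proteins, antigen presentation, TLR4 signalling components, the inflammasome, phagocyte oxidase and Fc receptors, chemokine receptors and adhesion molecules, NRF2 target genes, the unfolded protein and integrated stress response, cholesterol synthesis, the cell cycle, immediate early and heat shock genes, and markers of Ly6C-high monocytes, Ly6C-low monocytes, neutrophils, myeloid progenitors, macrophages, dendritic cells, B cells, T and NK cells, erythroid cells, eosinophils with basophils and mast cells, and megakaryocytes with platelets. Some genes are in several lists. Lists with at least 5 measured members (30 lists) were compared with the other genes by camera (limma 3.58.1) on log2 CPM with a preset correlation between genes of 0.01, adjusted over the lists, and again with the correlation estimated per list. fry was run as a self-contained test of whether a list moves on balance in 1 direction. Members were also adjusted over the list alone.

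The rule for the genes named was fixed at the same time. It took up to 10 called genes per direction and contrast with the largest fold changes, a mean of at least 10 CPM in the higher group and no overlap of the groups, leaving out predicted genes, clone names, ribosomal protein, mitochondrial, immunoglobulin and T-cell receptor genes, then up to 4 members of each list with the smallest p, and 17 genes of interest whether called or not. Rps6ka2 encodes a kinase and was kept. Genes that passed only adjusted over their list alone or in another tool are named beyond that rule and were chosen after their values were seen. A gene that the rule selects from 1 list is not reported here.

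Alternatives planned before the data were examined were no filter, a stricter filter (at least 1 CPM in at least 6 libraries), relative log expression scaling (RLE), library size alone, DESeq2 1.42.0, limma-voom, a fit of only the 2 groups compared, the replicate number as a block, each library left out in turn, and for lists the estimated correlation and fry. Alternatives for normalised units did not apply to counts. Added after seeing the data were the library class as a covariate, only the 7 libraries of 1 class, and offsets that remove a loess trend (span 0.5) over GC content and length (14314 genes). The class came from 5 genes and a log2 CPM boundary of 2.34.

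Whether replicate numbers pair the samples was checked by correlating the deviations of same-numbered libraries from their group means. Between the unstimulated groups the correlations were 0.26, 0.12 and 0.20, each library correlating best with its own number, so the numbers were taken to pair these samples. That pairing rests on the data, not on the labels. In both unstimulated groups replicate 1 was in 1 library class and replicates 2 and 3 in the other. A shared class could thus account for part of these correlations, and the pairing is not certain. The other pairs of groups did not meet the same rule. Among them, control unstimulated libraries also correlated best with their own number in the succinate LPS group, but weakly (0.04 to 0.1).

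The functions were tested on simulated counts with 200 changed genes, as many raised as lowered. These were drawn only from the better expressed genes, so the shares called do not cover genes with few counts. In the simulated LPS contrast of control mice (13985 genes), 32.8% of changes of 1.5-fold, 86.6% of 2-fold and 97% of 4-fold were called, with 11 false calls among 155. In the simulated succinate contrast with LPS (13994 genes) the shares were 29.9%, 67.2% and 97%, with 4 false calls among 133. A list raised 1.5-fold was found by camera in both, with 1 false call of an unchanged list in the LPS contrast and 0 in the other. Simulated genes were drawn independently of one another, so false calls of lists whose members move together were not covered. Overlap of called genes was set against n1 × n2 / N. Joining and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.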

Results

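Monocytes were isolated from mouse bone marrow as cells carrying the myeloid integrin CD11b and a high level of Ly6C, the surface marker of classical inflammatory monocytes. The donor animals had received 300 mM succinate for 7 days or no succinate. Succinate is an intermediate of the tricarboxylic acid (TCA) cycle that also acts on cells from outside through the receptor Sucnr1. After sorting, the cells were cultured without a stimulus or for 4 h with lipopolysaccharide (LPS), the bacterial ligand of Toll-like receptor 4 (TLR4). RNA-seq gave read counts per gene for 12 libraries, 3 in each of 4 groups: control mice without LPS, control mice with LPS, succinate mice without LPS and succinate mice with LPS. Total counts per library lay between 15975882 and 18306747, with a median of 16980357, and between 19429 and 21183 genes had at least 1 count. The labels do not say whether the 3 libraries of a group came from separate mice, so the p-values measure only the spread between these samples, which may be technical. Levels are given as CPM (counts scaled to a common library total after normalisation), mean ± SD over n = 3 libraries, and changes as log2 fold changes ± SE, with adjusted p-values from edgeR's quasi-likelihood test unless another tool is named.

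The libraries parted first by LPS. The first principal component held 61.6% of the variance and separated the 6 LPS libraries from the 6 unstimulated ones, while the second held 8.1% and did not separate the mice by succinate. Counts of 5 genes (S100a4, Rpl24, Rpl10-ps3 and the processed pseudogenes Gm14303 and Rpl35a-ps2) divided the libraries in another way. Their mean log2 CPM was 3.23 to 4.02 in 5 libraries (replicates 2 and 3 of both unstimulated groups and replicate 3 of the control LPS group) and 0.84 to 1.45 in the other 7, which included all 3 libraries of succinate mice with LPS. These are called the 2 library classes here. Between the LPS groups, keeping only 1 class thus leaves out just replicate 3 of the control LPS group. It is not a separate check from leaving out that library. The mitochondrially encoded share of counts was 0.960 ± 0.046% in unstimulated control cells, 0.963 ± 0.060% in unstimulated cells of succinate mice, 1.03 ± 0.046% in control cells with LPS and 1.243 ± 0.021% in cells of succinate mice with LPS. The ribosomal protein share was 3.257 ± 0.353%, 3.34 ± 0.573%, 3.123 ± 0.072% and 3.817 ± 0.095% in the same order. Scaling by library size alone, in place of trimmed means, moved the median log2 fold change of all genes between the LPS groups from -0.014 to 0.107. Changes below are relative to the trimmed-mean scaling.

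The first comparison asked how monocytes of control mice answered LPS. The acute-phase protein Saa3 rose from 1.65 ± 0.581 to 622 ± 89.6 CPM (log2 fold change 8.54 ± 0.33, adjusted p = 4.04e-10), and the T-cell-attracting chemokine Ccl5 rose from 0.806 ± 0.399 to 246 ± 43.4 CPM. Interleukin 10 (Il10), the main anti-inflammatory cytokine of macrophages, rose from 0.475 ± 0.25 to 96.3 ± 16.7 CPM (7.63 ± 0.34, adjusted p = 9.66e-10). Acod1, the enzyme that makes itaconate from the TCA cycle intermediate cis-aconitate, rose from 165 ± 26.8 to 4300 ± 517 CPM (4.70 ± 0.23, adjusted p = 2.33e-09). In all, 2190 genes rose and 2116 fell of 14324 tested (30.06%), of which 1196 and 888 changed at least 2-fold.

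Among the largest rises, the soluble pattern recognition molecule Ptx3 (chromosome 3, 66219910 to 66225805, GRCm38) had no count without LPS and 47.7 ± 5.3 CPM with it, at least 792-fold higher. Slamf1, a receptor of activated immune cells, likewise had no count without LPS and 10 ± 2.91 CPM with it, at least 167-fold higher. The RNA-binding protein gene Rbm24 had 1 count without LPS, giving a ratio of 744 (95% counting interval 133 to 29400), and the inducible nitric oxide synthase Nos2 had 3 counts, giving a ratio of 261 (89.1 to 1270). These floors and intervals cover counting error only. Il1a rose by 8.01 ± 0.54, the activating receptor Tarm1 by 7.39 ± 0.35 and Il6 by 7.23 ± 0.55 (log2). The largest falls were those of Hpgd, which inactivates prostaglandins (-5.22 ± 0.65, adjusted p = 1.84e-05), Fblim1 (-4.86 ± 0.45), Wwc1 (-4.31 ± 0.38), the calpain Capn5 (-4.12 ± 0.29), Snx24 (-4.05 ± 0.37), Fam102a (-3.98 ± 0.21), Engase (-3.92 ± 0.50), the gamma-secretase subunit Aph1c (-3.88 ± 0.22), the lysophosphatidic acid receptor Lpar6 (-3.86 ± 0.24) and the phosphatidate phosphatase Lpin1 (-3.81 ± 0.31). Aph1c went from 102 ± 6.51 to 6.92 ± 0.765 CPM.

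Of 29 measured inflammatory cytokines and chemokines, 27 rose, 1 fell and 1 did not pass, with the same counts adjusted over the list alone. Ccl4 rose from 10.1 ± 1.11 to 600 ± 25.5 CPM, Il1b from 6.09 ± 2.30 to 609 ± 444 CPM (6.64 ± 0.51, adjusted p = 1.71e-07) and Tnf from 50.7 ± 1.76 to 449 ± 78.6 CPM (3.15 ± 0.19). The list's median log2 fold change was 4.65, or 4.30 with members near 0 counts set at their bound. All 35 measured interferon-stimulated genes rose, with a median of 3.18 (3.09 with members at their bound), as did all 35 adjusted over the list alone. The antiviral Rsad2 (viperin) rose from 9.30 ± 0.711 to 480 ± 84.9 CPM, Oasl1 from 1.94 ± 0.748 to 140 ± 26.2 CPM and the chemokine Cxcl10 from 5.24 ± 1.37 to 437 ± 53.6 CPM. Of 20 feedback regulators of inflammation, 16 rose and 1 fell (18 and 1 adjusted over the list alone), among them the cytokine-signalling inhibitor Socs3 (5.06 ± 0.20) and the ubiquitin-editing enzyme Tnfaip3 (3.82 ± 0.19). All 3 lists stood above the other genes in camera with a preset correlation of 0.01 (adjusted p = 4.84e-21, 3.19e-28 and 2.45e-15). With an estimated correlation, the cytokine list held in both LPS comparisons (adjusted p = 0.0164 here) and no other camera call in any of the 5 comparisons did. For interferon-stimulated genes and for feedback regulators, adjusted p = 0.117 with an estimated correlation.

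Genes of the IL-4 receptor axis and of hypoxia-inducible factor 1 (HIF-1) were of interest because the series names both. Il4ra, the receptor's alpha chain (chromosome 7, 125552120 to 125579474), rose from 73.2 ± 10.2 to 221 ± 86.7 CPM (1.59 ± 0.22, adjusted p = 4.92e-05). Its transcription factor Stat6 fell from its unstimulated level by 0.41 ± 0.10 on the log2 scale (adjusted p = 0.00478). Of the 10 components of IL-4 receptor signalling, 6 rose and 2 fell (7 and 2 adjusted over the list alone), with the kinase Tyk2 up by 1.98 ± 0.16, the common gamma chain Il2rg up by 1.58 ± 0.17 and the adaptor Irs2 at -1.39 ± 0.16. The list's median was 0.84 (camera adjusted p = 0.0482; adjusted p = 0.435 with an estimated correlation), and the call was lost with a stricter filter and without any of 5 single libraries. IL-4 target genes of alternative activation went both ways, 6 up and 3 down of 15 measured (6 and 4 adjusted over the list alone; median 0.23, camera adjusted p = 0.375). Transglutaminase Tgm2 rose by 2.77 ± 0.21 and Cish by 3.97 ± 0.42, while the transcription factors Klf4 (-2.08 ± 0.15) and Pparg (-3.47 ± 0.29) fell. The IL-4 target Arg1, with 60 counts over all 12 libraries, and the succinate receptor Sucnr1 (chromosome 3, 60081869 to 60087566), with 2, were too low to test.

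Hif1a itself (chromosome 12, 73901375 to 73947530) went from 227 ± 8.91 to 292 ± 19.7 CPM (0.36 ± 0.13, adjusted p = 0.0466), a rise called in 11 of 23 settings. Of 30 measured HIF-1 targets, 7 rose and 9 fell (7 and 10 adjusted over the list alone; median -0.05, camera adjusted p = 0.885). The mTORC1 inhibitor Ddit4 rose by 1.69 ± 0.20 and Ndrg1 by 1.23 ± 0.15, while the mitophagy receptor Bnip3l fell (-0.63 ± 0.11). Vegfa did not pass (-0.05, adjusted p = 0.831). Glycolysis had 4 risers and 5 fallers of 22, both over all genes and adjusted over the list alone (median 0, adjusted p = 0.954). The glucose transporter Slc2a1 rose by 1.03 ± 0.18 and the lactate dehydrogenase Ldha by 0.53 ± 0.14, and the lactate exporter Slc16a3 fell (-1.03 ± 0.18).

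Other groups of immune genes also moved. Of 16 phagocyte oxidase and Fc receptor genes 10 rose and 2 fell (median 0.68, camera adjusted p = 0.00157; adjusted p = 0.435 with an estimated correlation). The oxidase subunit Cybb rose from 1010 ± 71.4 to 4280 ± 225 CPM and the scavenger receptor Cd36 fell (-3.26 ± 0.25). Of 14 targets of the oxidative stress factor NRF2, 12 rose (14 adjusted over the list alone; median 1.40, camera adjusted p = 6.29e-06; adjusted p = 0.435 with an estimated correlation), with the ferritin heavy chain Fth1 going from 7610 ± 954 to 16200 ± 1680 CPM. Of 14 inflammasome genes 7 rose and 2 fell (median 0.75, adjusted p = 0.0104; adjusted p = 0.183 with an estimated correlation), led by the sensor Nlrp3 (2.62 ± 0.17). Of 22 components of TLR4 signalling 9 rose and 2 fell (median 0.22, adjusted p = 0.00796; adjusted p = 0.418 with an estimated correlation), led by Nfkb1 (2.21 ± 0.14). For every list, the count adjusted over the list alone equalled the count over all genes where only 1 count is given. Chemokine receptors and adhesion molecules had 8 up and 6 down of 20 (9 and 7 adjusted over the list alone), with Icam1 at 3.87 ± 0.18 and the marrow-retention receptor Cxcr4 at -1.73 ± 0.13. Antigen presentation had 4 up and 2 down of 13, with the co-stimulator Cd40 up by 5.07 ± 0.27 and Cd86 at -0.62. That list's median was -0.09 while its mean was 0.78 and its test pointed up (adjusted p = 0.375).

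Of the TCA cycle list 2 rose and 1 fell of 23 (2 and 0 adjusted over the list alone), with dihydrolipoamide dehydrogenase Dld at 0.77 ± 0.10. Of the nuclear-encoded respiratory chain 1 of 42 rose and 1 fell, of the mitochondrially encoded genes 1 of 12 rose, and of the ribosomal proteins 0 of 35 were called by edgeR (camera adjusted p = 0.508, 0.309 and 0.973). Ribosomal protein genes, Fth1 and Gapdh have many processed pseudogenes, so their counts are uncertain where reads could be split among copies. The unfolded protein and integrated stress response had 4 up and 2 down of 17, cholesterol synthesis 2 up of 20, the cell cycle 2 up and 3 down of 26 (0 and 3 adjusted over the list alone), and immediate early and heat shock genes 4 up and 5 down of 18, including Fos at -2.45 ± 0.14 and Jun at -2.04. The median of the TCA cycle, stress response and cell cycle lists, each within 0.04 of 0, changed sign with library size alone.

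Markers of monocyte states and of other marrow cells were read in the same way. Ly6C-high monocyte markers had 3 up and 6 down of 16 (3 and 7 adjusted over the list alone), with haptoglobin Hp up by 2.71 ± 0.14 and the coagulation factor F13a1 at -1.76. Ly6C-low markers had 4 up and 5 down of 12, neutrophil markers 8 up and 2 down of 15, myeloid progenitor markers 3 up of 11 (4 adjusted over the list alone), and dendritic cell markers 5 up of 9. Macrophage markers had 3 up of 6 (camera adjusted p = 0.0347; adjusted p = 0.183 with an estimated correlation), among them the adhesion molecule Vcam1 (2.60 ± 0.13), a call that held in 12 of 21 settings. B-cell markers had 1 of 10 called, Ighm at -0.69, erythroid markers 1 of 6, the carbonic anhydrase Car2 at 2.60, and eosinophil, basophil and mast cell markers 2 of 9. The T and NK cell list and the megakaryocyte list had 4 and 2 measured members and were not tested as lists.

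**Figure D1:**
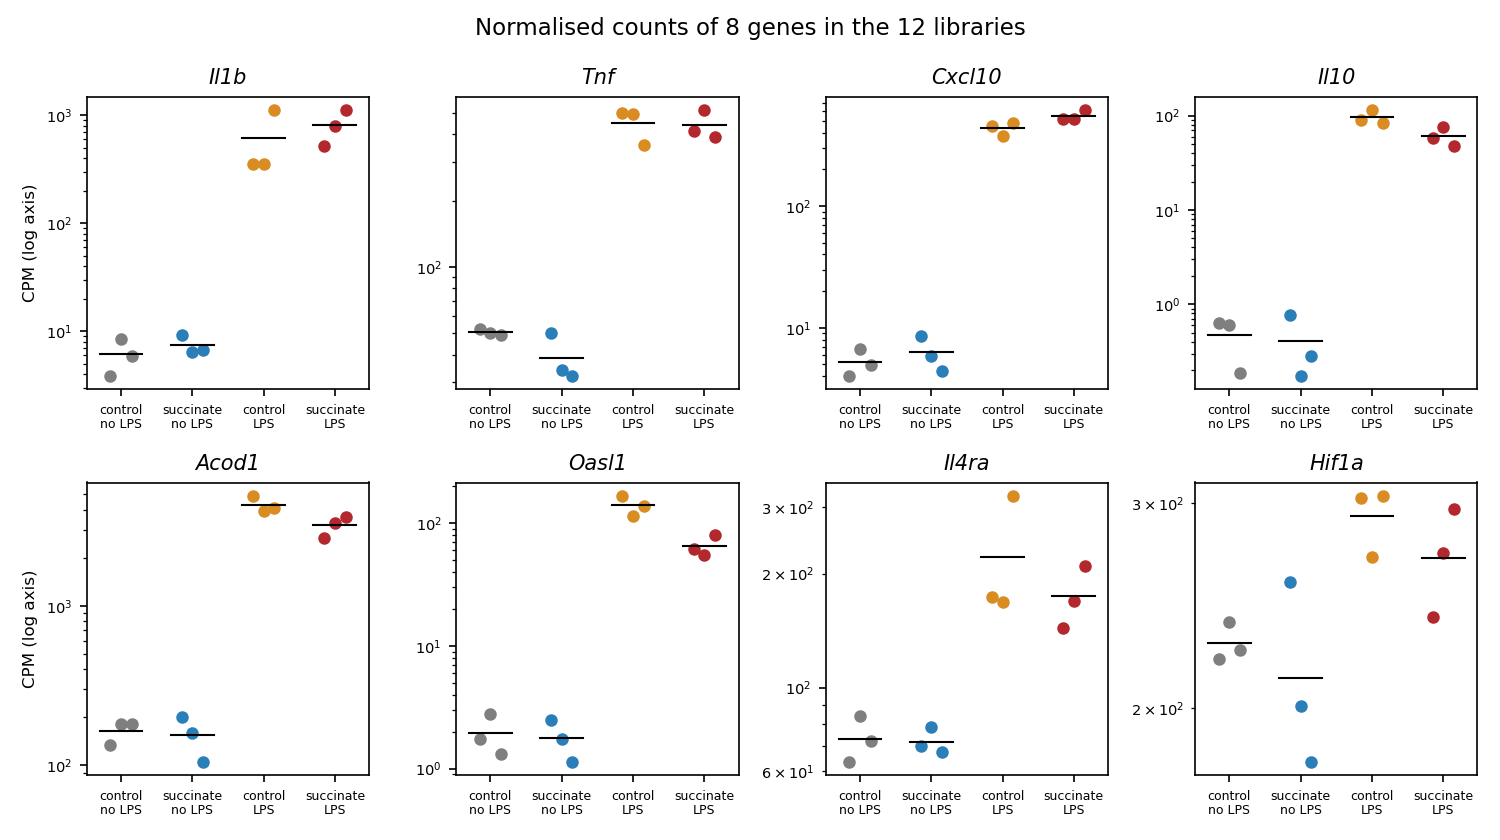
Normalised counts (CPM, log axis) of 8 genes in each of the 12 libraries. Points are libraries, 3 per group, and bars are group means. Il1b, Tnf, Cxcl10, Il10, Acod1, Oasl1 and Il4ra were called higher with LPS in both kinds of mice, and none of the 8 was called between control and succinate mice.

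Monocytes of succinate mice answered LPS with 2013 genes rising and 2318 falling (30.24% of 14324), 1019 and 967 of them at least 2-fold. The same mediators rose. Il1b rose from 7.45 ± 1.49 to 807 ± 297 CPM (6.76 ± 0.51, adjusted p = 1.45e-07), Il6 from 0.391 ± 0.359 to 38.3 ± 14.0 CPM (6.60 ± 0.49) and Cxcl10 from 6.28 ± 2.16 to 550 ± 56.7 CPM (6.45 ± 0.24, adjusted p = 4.86e-10). Il10 rose from 0.408 ± 0.313 to 60.8 ± 14.7 CPM (7.20 ± 0.35) and Acod1 from 155 ± 47.4 to 3200 ± 478 CPM (4.37 ± 0.23). Il4ra rose from 72.0 ± 5.93 to 174 ± 33.4 CPM (1.28 ± 0.22, adjusted p = 0.000371). Hif1a, at 212 ± 39.5 and 269 ± 28.4 CPM, did not pass (0.34 ± 0.13, adjusted p = 0.0596), though it was called in 9 of 23 settings.

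Ptx3 had 1 count without LPS, giving a ratio of 3560 (639 to 141000), Nos2 had 3, giving 538 (184 to 2610), Rbm24 gave 297 (81.8 to 2460) and the chemokine Ccl22 232 (79.2 to 1130). The survival factor Bcl2a1a rose by 8.66 ± 0.48, a value that is uncertain because its family holds near-identical copies. Saa3 rose by 7.74 ± 0.31, the neutrophil attractant Cxcl1 by 7.48 ± 0.62, Il1a by 7.22 ± 0.50 and Ccl5 by 6.96 ± 0.38. The largest falls were those of Wwc1 (-5.76 ± 0.43), Hpgd (-5.40 ± 0.66), Fblim1 (-5.29 ± 0.49), the endolysosomal channel Mcoln3 (-4.34 ± 0.39), Fam102a (-4.14 ± 0.21), Capn5 (-4.11 ± 0.29), the sugar phosphate transporter Slc37a2 (-4.08 ± 0.32), Lpin1 (-4.05 ± 0.30), Stra6l (-3.87 ± 0.27) and Aph1c (-3.83 ± 0.22). Stat6 fell (-0.38 ± 0.10, adjusted p = 0.00775), Ldha rose by 0.49 ± 0.14, and Slc2a1 did not pass (0.43 ± 0.18, adjusted p = 0.0905). Vegfa fell (-0.41 ± 0.14, adjusted p = 0.0435), a call made in 9 of 23 settings.

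Of the 29 cytokines and chemokines, 27 rose and 1 fell (27 and 2 adjusted over the list alone; median 4.06, camera adjusted p = 6.33e-21; adjusted p = 0.0167 with an estimated correlation). Of the 35 interferon-stimulated genes 33 rose (34 adjusted over the list alone; median 2.85, adjusted p = 1.17e-24; adjusted p = 0.153 with an estimated correlation), with Rsad2 at 4.93 ± 0.25 and Oasl1 at 5.20 ± 0.27. Feedback regulators had 16 up and 1 down (median 2.18, adjusted p = 5.2e-13; adjusted p = 0.153 with an estimated correlation). Phagocyte genes had 10 up and 2 down (median 0.67, adjusted p = 0.00515; adjusted p = 0.512 with an estimated correlation) and inflammasome genes 7 up and 1 down (7 and 3 adjusted over the list alone; median 0.57, adjusted p = 0.0114; adjusted p = 0.201 with an estimated correlation). NRF2 targets had 7 up of 14 (median 0.74, adjusted p = 0.00643; adjusted p = 0.699 with an estimated correlation), with Fth1 at 0.76 ± 0.15 and the cystine transporter Slc7a11 at 1.36 ± 0.30. That call was lost with the library class as a covariate (median 0.29) and within 1 class (0.41). The nuclear-encoded respiratory chain had 7 up and 1 down of 42 (6 and 1 adjusted over the list alone; median 0.28, adjusted p = 0.00643; adjusted p = 0.812 with an estimated correlation), led by Ndufb3 (1.24 ± 0.20), and lost its call in the same 2 settings (0.13 and 0.08) and without replicate 2 of the unstimulated succinate group. Mitochondrially encoded genes had 5 up of 12 (6 adjusted over the list alone; median 0.38, adjusted p = 0.0114; adjusted p = 0.512 with an estimated correlation), with mt-Cytb at 0.40 ± 0.10, a call lost after removing GC and length trends. Macrophage markers had 3 up of 6 (median 1.09, adjusted p = 0.0164; adjusted p = 0.153 with an estimated correlation), and myeloid progenitor markers 5 up of 11 (5 and 1 down adjusted over the list alone; median 0.42, adjusted p = 0.0269; adjusted p = 0.699 with an estimated correlation), with the stem cell factor receptor Kit up by 1.83 ± 0.16.

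The remaining lists were not called by camera in succinate mice. IL-4 receptor components had 4 up and 2 down of 10 (5 and 2 adjusted over the list alone; median 0.52, adjusted p = 0.0866), IL-4 targets 7 up and 4 down of 15 (8 and 4; median 0.45), HIF-1 targets 4 up and 8 down of 30 (median -0.11) and glycolysis 2 up and 4 down of 22 (median -0.08). IL-4 receptor components passed with the library class as a covariate (median 0.95, adjusted p = 0.0329). TLR4 components had 6 up and 1 down of 22 (7 and 3 adjusted over the list alone), antigen presentation 4 up and 2 down of 13, chemokine receptors and adhesion molecules 6 and 6 of 20 (7 and 6), the stress response 3 and 2 of 17, cholesterol synthesis 1 and 1 of 20 (0 and 0), the cell cycle 5 and 3 of 26, immediate early genes 1 and 4 of 18 and the TCA cycle 1 and 1 of 23 (1 and 0), with counts adjusted over the list alone in parentheses. Ly6C-high markers had 3 up and 7 down of 16 (4 and 8), Ly6C-low markers 4 and 3 of 12 (5 and 4), neutrophil markers 7 and 2 of 15, dendritic cell markers 4 up of 9 (6 and 1 down), B-cell markers 1 down of 10 (Ighm at -0.65; 0 adjusted over the list alone), T and NK cell markers 2 up of 4 (Nkg7 at 0.83 and Lck at 1.01), erythroid markers 1 up of 6, and eosinophil, basophil and mast cell markers 3 up of 9. Ribosomal proteins (35) and megakaryocyte markers (2) had 0 called by edgeR.

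The LPS responses of both kinds of mice shared most of their genes. These comparisons have no library in common. Across 14324 genes, which are not independent replicates, the log2 fold changes correlated with Pearson's r = 0.87 and Spearman's rho = 0.79. Of the genes called, 1615 rose in both (307.8 would overlap for independent lists) and 1701 fell in both (342.4). The predicted gene Gm10705 (chromosome 3, 87207545 to 87208005) was called in opposite directions, at 1.56 ± 0.37 in control and -1.24 ± 0.35 in succinate mice (adjusted p = 0.00521 and 0.0149), and is named here after its values were seen. Calls made in control mice alone numbered 989 and in succinate mice alone 1014, but none of them was called in the test of the difference. Within the 7 libraries of 1 class, with 1 unstimulated library per kind of mouse, 1211 genes rose and 887 fell in control mice, and 1143 and 1077 in succinate mice.

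**Figure D2:**
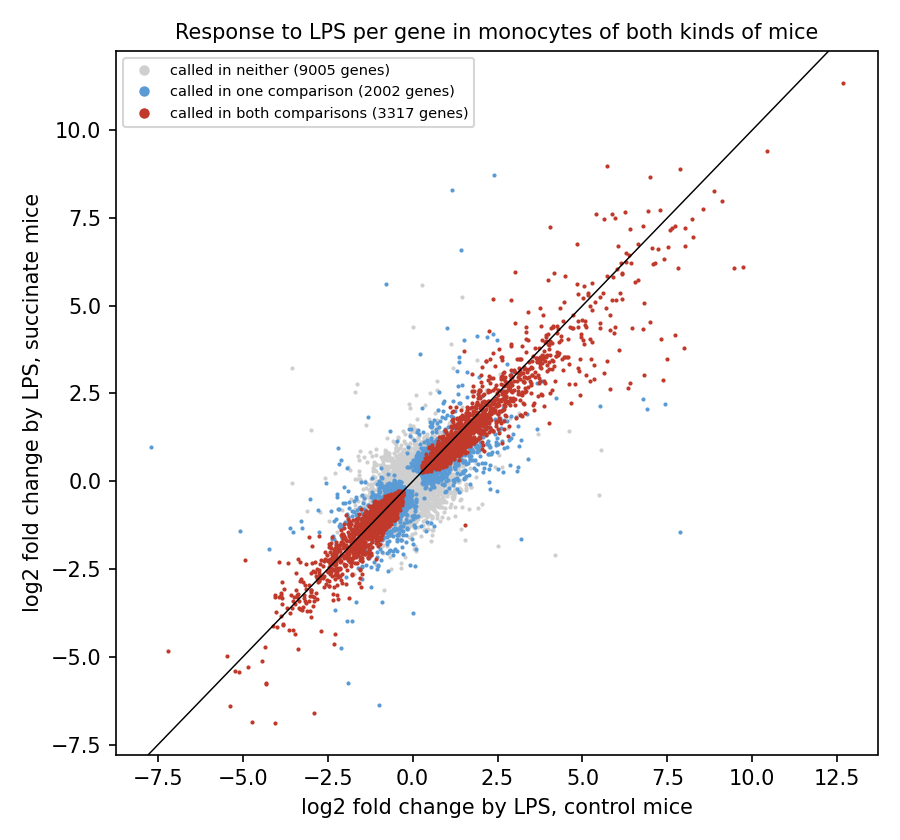
Log2 fold change by LPS in monocytes of control mice (x axis) and succinate mice (y axis), 1 point per tested gene, coloured by the number of comparisons in which it was called, with the line of equality. Of the 3317 genes called in both, all but 1 (Gm10705) changed in the same direction. The largest values, those of Ptx3 and Slamf1, belong to genes with 0 or 1 count in unstimulated cells, where the fitted value depends on the prior count.

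Without LPS, edgeR called 0 genes between monocytes of succinate and control mice, with a smallest adjusted p of 0.601. With no filter it called 34 higher and 38 lower. At an unadjusted p under 0.05 there were 535 genes (296 higher, 239 lower), against 716 expected by chance, and the balance depended on the scaling (266 and 276 with relative log expression, 380 and 171 with library size alone, 274 and 342 with GC and length trends removed). With the replicate number as a block, which takes up the pairing inferred for these samples, there were 792 (388 higher, 404 lower). limma-voom also called 0, and DESeq2 called 1, the predicted gene Gm10705, higher in succinate mice (2.15 ± 0.36, DESeq2 adjusted p = 8.4e-05). Il4ra was at 72.0 ± 5.93 CPM in succinate and 73.2 ± 10.2 CPM in control mice, with a 95% interval of the log2 difference from -0.49 to 0.44, so changes beyond these bounds were excluded at this spread. For Hif1a the interval ran from -0.37 to 0.18, for Tnf from -0.76 to 0 and for Acod1 from -0.52 to 0.34.

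Gene lists gave weak shifts without LPS. B-cell markers lay higher in succinate mice in 9 of 10 members (median 0.57, camera adjusted p = 8.99e-05; adjusted p = 0.551 with an estimated correlation). Cd79b, a chain of the B-cell receptor, was at 8.80 ± 1.19 against 5.89 ± 2.10 CPM, and the immunoglobulin heavy chain gene Ighm at 177 ± 32.0 against 128 ± 9.81 CPM. Ly6C-high monocyte markers lay lower in 14 of 16 members (median -0.32, adjusted p = 0.00156; adjusted p = 0.995 with an estimated correlation), as with the pore-forming protein gene Mpeg1 (-0.48), and nuclear-encoded respiratory chain genes in 38 of 42 (median -0.12, adjusted p = 0.000202; adjusted p = 0.995 with an estimated correlation). Phagocyte genes (median -0.18, adjusted p = 0.0158; adjusted p = 0.995 with an estimated correlation), Ly6C-low markers (-0.28, adjusted p = 0.0233; adjusted p = 0.734 with an estimated correlation) and macrophage markers (-0.27, adjusted p = 0.0447; adjusted p = 0.551 with an estimated correlation) were also called lower. No member of these 6 lists passed over all genes, and adjusted over the list alone only Vcam1 did, among macrophage markers (-0.40 ± 0.13). Leaving out replicate 2 of the unstimulated succinate group ended the calls of the Ly6C-high, Ly6C-low, respiratory chain and phagocyte lists, and the respiratory chain median changed sign. The macrophage call held in 9 of 21 settings, with an adjusted p of 0.0569 when replicate number was added as a block. HIF-1 targets (median 0.05), glycolysis (0.05), IL-4 targets (-0.10), IL-4 receptor components (-0.07), cytokines (0.11) and interferon-stimulated genes (-0.11) were not called.

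With LPS, 9 genes were lower in monocytes of succinate mice than in those of control mice and none was higher by edgeR. All 9 are named here. Por, the reductase that passes electrons to microsomal cytochrome P450 enzymes (chromosome 5, 135670033 to 135735326), was at 284 ± 17.4 against 472 ± 28.5 CPM (-0.73 ± 0.10, adjusted p = 0.0221). Cyp4f18, a P450 that hydroxylates leukotriene B4 (chromosome 8, 71988482 to 72009626), was at 65.1 ± 3.75 against 119 ± 1.87 CPM (-0.87 ± 0.12, adjusted p = 0.0221). The ribosomal S6 kinase gene Rps6ka2 (chromosome 17, 7170115 to 7303315) was at 100 ± 6.61 against 175 ± 6.33 CPM (-0.80 ± 0.10, adjusted p = 0.0221). Fnip2, a partner of folliculin in amino acid sensing, was at 241 ± 32.6 against 400 ± 38.1 CPM (-0.73 ± 0.12). The others were the von Willebrand factor gene Vwf (-1.36 ± 0.21), the creatine transporter Slc6a8 (-0.95 ± 0.14), Rusc2 (-0.88 ± 0.13), the zinc finger gene Zfp503 (-0.81 ± 0.13) and the kinesin Kif1c (-0.72 ± 0.12), with adjusted p-values from 0.0261 to 0.0461.

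The number called depended on the tool and on single libraries. Leaving out 1 library gave from 0 to 181 lower genes, with 0 for any of 5 libraries and 181 without replicate 3 of the succinate LPS group. At an unadjusted p under 0.05 there were 1680 genes, 508 higher and 1172 lower, against 716 expected by chance, but 1482 higher and 644 lower with library size alone. Other splits of these 6 libraries, which mix the groups, gave 193 to 1450, so the excess over 716 does not by itself show an effect of succinate. DESeq2 called 23 higher and 317 lower, including all 9, and limma-voom 0 and 34. With the library class as a covariate 19 were higher and 171 lower, and within 1 class 1 was higher and 0 lower. The 9 genes had a median log2 fold change of -0.81 as reported, -0.81 with the covariate, -0.83 within 1 class and -0.69 with library size alone, where none of the 9 was called.

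Inflammatory cytokines did not separate the LPS groups. Il1b was at 807 ± 297 in succinate against 609 ± 444 CPM in control mice, Il6 at 38.3 ± 14.0 against 28.2 ± 3.98 CPM and Tnf at 439 ± 68.1 against 449 ± 78.6 CPM, and none passed. The Tnf interval ran from -0.40 to 0.33, and its sign turned with library size alone. Those of Il1b (-0.42 to 1.24) and Il6 (-0.24 to 1.13) were wider, so equal levels were not shown. The list's median was -0.03, its mean 0.10 and its test pointed up (adjusted p = 0.753). Il10 was at 60.8 ± 14.7 against 96.3 ± 16.7 CPM (-0.66 ± 0.22, unadjusted 95% interval -1.12 to -0.2, adjusted p = 0.227, with 0.00119 to 0.661 over the other settings). Nos2 was at 31.2 ± 1.62 against 15.8 ± 10.6 CPM (0.98 ± 0.33, interval 0.27 to 1.7, adjusted p = 0.248, with 9.08e-05 to 0.727 over the other settings). Without replicate 3 of the control LPS group, the only LPS library of its class, the Nos2 difference was 1.69 (adjusted p = 0.00985). The fit within 1 class compares the same LPS libraries, so its 1.69 is not a separate result. Without replicate 1 or 2 of that group it was 0.73 (adjusted p = 0.727) and 0.72 (adjusted p = 0.469). Acod1 (-0.43, interval -0.85 to 0, adjusted p = 0.424), Il4ra (-0.34, interval -0.80 to 0.11, adjusted p = 0.58) and Hif1a (-0.12, interval -0.39 to 0.16, adjusted p = 0.789) did not pass.

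Interferon-stimulated genes lay lower in 2 of the 3 LPS libraries of succinate mice. The list's mean score per library (log2, centred) was 1.05, 1.01 and 1.69 in succinate and 2.04, 1.49 and 1.72 in control mice, so replicate 3 of the succinate group lay within the control range. Of 35 members, 32 lay lower, with a median of -0.65 (camera adjusted p = 4.29e-10; adjusted p = 0.661 with an estimated correlation). Over all genes none passed, and adjusted over the list alone 12 fell and 1 rose. Oasl1 was at 65.8 ± 13.1 against 140 ± 26.2 CPM, Rsad2 at 258 ± 43.0 against 480 ± 84.9 CPM and the RNA sensor Ifih1 at 99.2 ± 23.7 against 172 ± 24.9 CPM (-1.09 ± 0.21, -0.89 ± 0.20 and -0.79 ± 0.17, adjusted p over all genes 0.0547, 0.0793 and 0.0679), while the chemokine Cxcl11 was at 1.42 ± 0.456 against 0.420 ± 0.254 CPM. Within 1 class the median was -0.58. Feedback regulators had a median of -0.34 (adjusted p = 0.000153; adjusted p = 0.661 with an estimated correlation), and 9 of 20 fell adjusted over the list alone, 0 over all genes. These included the phosphatase Dusp1 (136 ± 23.3 against 219 ± 24.2 CPM), the interleukin 1 receptor antagonist Il1rn (1870 ± 730 against 3180 ± 413 CPM) and the checkpoint ligand Cd274 (344 ± 72.6 against 498 ± 90.9 CPM). NRF2 targets lay lower in 13 of 14 members (median -0.54, or -0.34 without replicate 1 of the control LPS group, adjusted p = 3.57e-05; adjusted p = 0.661 with an estimated correlation), and the ferritin genes Fth1 (11300 ± 901 against 16200 ± 1680 CPM) and Ftl1 (2580 ± 56.9 against 3500 ± 539 CPM) fell adjusted over the list alone.

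All 10 components of IL-4 receptor signalling lay lower (median -0.26, adjusted p = 0.0117; adjusted p = 0.661 with an estimated correlation), with Il2rg at -0.48 ± 0.16, but none passed in either adjustment. That list was not called with the class covariate (median -0.19) or within 1 class (-0.16), nor without replicate 3 of the control LPS group or replicate 1 of the succinate LPS group. Of 15 IL-4 targets, 3 rose adjusted over the list alone and 0 over all genes: the lectin Mgl2 (19.5 ± 1.56 against 11.2 ± 3.52 CPM), the chemokine Ccl17 (3.69 ± 1.84 against 1.01 ± 0.320 CPM) and the transcription factor Irf4 (14.2 ± 2.81 against 8.86 ± 2.34 CPM). The list as a whole had a median of -0.27 and a mean of 0.04 (adjusted p = 0.753). Among HIF-1 targets (median 0.08, adjusted p = 0.553) Ndrg1 fell adjusted over the list alone (184 ± 31.6 against 300 ± 36.1 CPM), as did Pfkp in glycolysis (-0.39 ± 0.10, list median -0.06, adjusted p = 0.678), both with 0 over all genes. Vegfa (-0.43, unadjusted 95% interval -0.74 to -0.12) and Slc2a1 (-0.41, interval -0.79 to -0.02) lay lower but did not pass. For Ldha the interval ran from -0.37 to 0.21. Phagocyte genes (median -0.24, adjusted p = 0.0119) and TLR4 components (-0.10, adjusted p = 0.0301) were called lower, each with adjusted p = 0.661 with an estimated correlation. With library size alone the TLR4 median turned to 0.02, and those of feedback regulators, IL-4 receptor components, phagocyte genes and ribosomal proteins were -0.22, -0.14, -0.12 and 0.26. Neither the TLR4 nor the phagocyte list was called within 1 class or without replicate 3 of the control LPS group or replicate 1 of the succinate LPS group.

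Ribosomal protein genes lay higher in 34 of 35 members in succinate mice with LPS (median 0.14, adjusted p = 4.69e-06), as did B-cell markers in 10 of 10 (0.50, or 0.35 without replicate 2 of the control LPS group, adjusted p = 0.000153), cell cycle genes in 20 of 26 (0.15, adjusted p = 0.000409) and myeloid progenitor markers (0.22, adjusted p = 0.0211). For each of these 4 lists, adjusted p = 0.661 with an estimated correlation, and no member passed in either adjustment. Cd79b was at 8.16 ± 0.832 against 5.08 ± 0.134 CPM, Ighm at 113 ± 11.2 against 79.1 ± 29.0 CPM and the progenitor protease gene Prtn3 at 1140 ± 165 against 815 ± 256 CPM. The succinate LPS group also had the highest mean mitochondrial and ribosomal shares of counts and the largest mean total. Within 1 class the 4 medians were 0.15, 0.72, 0.22 and 0.40, and with library size alone 0.26, 0.62, 0.27 and 0.34. Without replicate 1 of the control LPS group the cell cycle and progenitor lists were not called, nor was the progenitor list without replicate 3 of the succinate LPS group. Members of 7 other lists passed adjusted over the list alone and not over all genes. Cd86 (-0.67 ± 0.16), the integrins Itgb7 (-0.72 ± 0.12) and Itgb2 (-0.39 ± 0.11), the scavenger receptor Msr1 (-0.62 ± 0.19), Asns (-0.40 ± 0.11), Junb (-0.43 ± 0.12) and Mpeg1 (-0.73 ± 0.20) fell, and the chaperone Hspa8 (0.62 ± 0.14) and the lymphocyte genes Nkg7 (0.52 ± 0.18) and Lck (0.97 ± 0.34) rose. The TCA cycle (median 0.02), the nuclear-encoded respiratory chain (0.08) and the mitochondrially encoded genes (0.11) were not called.

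**Figure D3:**
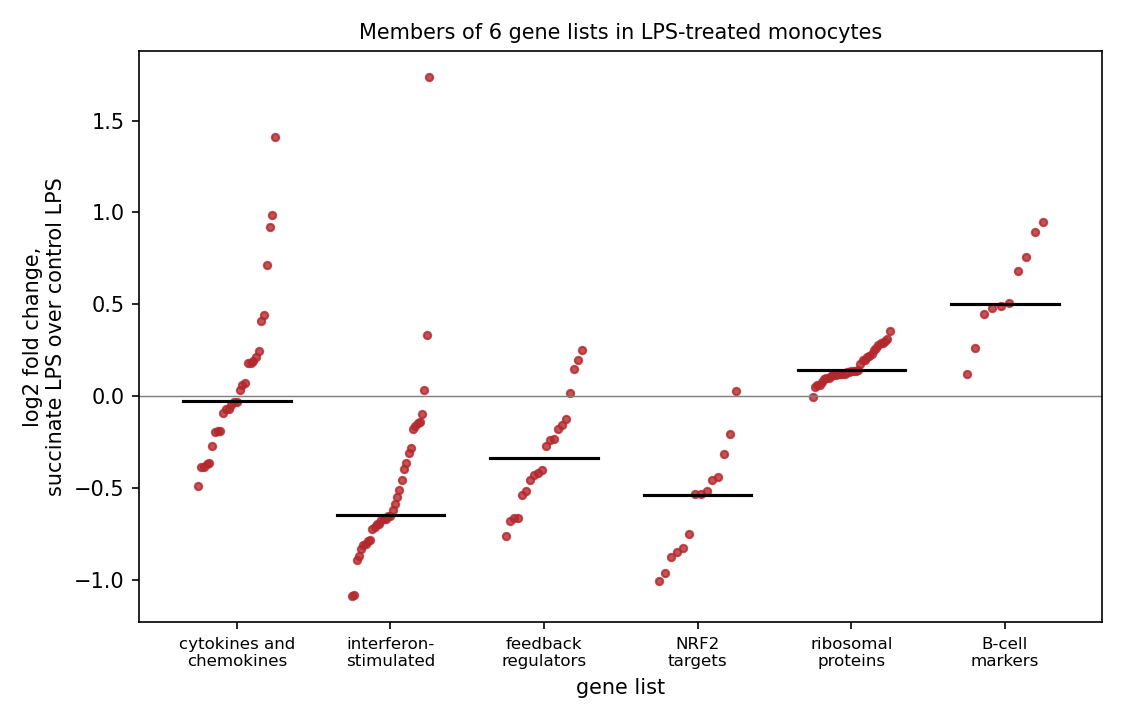
Log2 fold change between LPS-treated monocytes of succinate and control mice for each measured member of 6 gene lists (points, 3 libraries per group), with the list median (bars). Interferon-stimulated genes, feedback regulators and NRF2 targets centre at -0.65, -0.34 and -0.54, ribosomal proteins and B-cell markers at 0.14 and 0.50, and the cytokine median of -0.03 changes sign with library size alone.

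The last comparison tested whether the LPS response itself differed between succinate and control mice. edgeR called 0 genes, with a smallest adjusted p of 0.984, and 560 genes had an unadjusted p under 0.05 (135 higher, 425 lower; 290 and 237 with library size alone) against 716 expected by chance. With no filter edgeR called 22 higher and 49 lower. limma-voom called 0. DESeq2 called 3, all with a lower log2 change by LPS in succinate mice: the ubiquitin ligase gene Peli1 (-0.79, DESeq2 adjusted p = 0.0471), Rps6ka2 (-0.74, adjusted p = 0.0371) and Gm10705 (-2.80, adjusted p = 0.000972), named after their values were seen. For Il4ra the difference in response was -0.32 with an interval from -0.97 to 0.33, and for Hif1a it was -0.02 with an interval from -0.41 to 0.37. For Slc2a1 it was -0.6 (-1.15 to -0.06) and for Vegfa -0.36 (-0.79 to 0.08). These intervals are unadjusted, and neither of the last genes passed.

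Among lists, the response of interferon-stimulated genes was smaller in succinate mice (median difference -0.40, 31 of 35 lower, camera adjusted p = 1.93e-06, or 0.835 with an estimated correlation). Of 100 regroupings of the libraries, the real one included, 23 gave a median as large. The response was also smaller for NRF2 targets (-0.67, 14 of 14 lower, adjusted p = 5.49e-05), feedback regulators (-0.28), antigen presentation genes (-0.23) and TLR4 components (-0.15). It was larger for the nuclear-encoded respiratory chain (0.18, 39 of 42 higher, adjusted p = 5.32e-06), mitochondrially encoded genes (0.21), ribosomal proteins (0.14, 35 of 35 higher), cell cycle genes (0.15) and myeloid progenitor markers (0.23). All 10 lists had this adjusted p of 0.835 with an estimated correlation. The respiratory chain and ribosomal differences rested largely on replicate 2 of the unstimulated succinate group. Over the replicates of that group the list scores were 0.06, -0.51 and -0.06 for the respiratory chain and 0.19, -0.35 and 0.01 for ribosomal proteins. Within 1 class, with 1 unstimulated library per kind of mouse, the interferon and NRF2 medians were -0.69 and -0.85, and the respiratory chain (0.09) and ribosomal (0.02) lists were not called. With library size alone the medians of antigen presentation genes, TLR4 components, ribosomal proteins and cell cycle genes were -0.14, -0.06, 0.23 and 0.24. As reported, no list member passed over all genes. Adjusted over the list alone, Ndrg1 (-0.88 ± 0.21) and Itgb7 (-0.68 ± 0.17) responded differently. Cytokines (-0.14, adjusted p = 0.698), IL-4 targets (-0.04), IL-4 receptor components (-0.24), HIF-1 targets (-0.04), glycolysis (-0.09) and B-cell markers (0.01) were not called.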

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

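The tests that weigh the interferon pattern here, and the class settings, were chosen only after the result was seen. The splits of the samples and the left-out libraries were planned. Counts out of 10, 38 or 100 splits or regroupings include the real grouping.

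Each result in this part differed between control and succinate mice in its response to LPS, by camera on the interaction with a preset correlation. Medians of the difference were -0.40 for interferon-stimulated genes (adjusted p = 1.93e-06), -0.67 for NRF2 targets (5.49e-05), -0.28 for feedback regulators of inflammation (0.0104), -0.23 for antigen presentation (0.0425) and -0.15 for TLR4 signalling components (0.0425). They were 0.18 for the nuclear-encoded respiratory chain (5.32e-06), 0.21 for mitochondrially encoded genes (0.00371), 0.14 for ribosomal proteins (2.33e-05), 0.15 for the cell cycle (0.000458) and 0.23 for myeloid progenitor markers (0.0104). All 10 had an adjusted p of 0.835 with an estimated correlation, and fry called none. In 37 of 100 regroupings that split the unstimulated and the LPS libraries at random, as many lists or more were called, up to 18, so chance cannot be excluded for their number (15 of the 38 that part all 3 pairs of unstimulated libraries). Antigen presentation and TLR4 components lost their calls with the class covariate. The respiratory chain and ribosomal differences rested largely on succinate unstimulated 2, with list scores of -0.51 and -0.35. Replicates 1 and 3 of its group had 0.06 and -0.06 for the respiratory chain and 0.19 and 0.01 for ribosomal proteins. The interferon and NRF2 lists were called in all 20 other settings, but their medians ranged with 1 library left out from -0.70 (without succinate LPS 3) to -0.29 (without succinate LPS 1) and from -0.99 (without succinate unstimulated 3) to -0.32 (without control LPS 1).

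The interferon list was lower after LPS in succinate mice (median -0.65) and its response was smaller (-0.40). A single odd LPS library is argued against as the whole cause, since the median was at most -0.47 whichever of the 6 was left out. With library sizes alone the list's median was -0.53 and its upper quartile -0.18. That switch moved all genes by a near-constant amount (median of all genes -0.014 to 0.107). It could not undo a median of -0.65, so it shows only that the choice between these scalings is not the whole cause. Other errors of scaling were not tested for this list. An equal fall of all genes that LPS induces is argued against by the cytokine median of -0.03, above the upper quartile of the interferon list (-0.30). Weaker stimulation that lowers some of these genes more than others stays open. Feedback regulators (-0.34) and NRF2 targets (-0.54), which LPS also raised, lay lower as well. Chance stays open. For the interaction median 23 of 100 regroupings, the real one included, were as large (highest 0.834), as were 10 of the 38 that part the pairs. Some of these kept the LPS groups whole and so carried the real difference between them, with a median of up to 0.787. For the LPS groups the 10 possible splits are too few for a share under 0.05 (1 of 10 as large, real -0.652, highest other 0.635). A lower interferon arm after dietary succinate, with no called change in cytokines, may be an effect of the diet. That remains an untested hypothesis, as regroupings of the same libraries gave interaction medians as large.

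Of the 10 splits of the 6 libraries in each comparison of 2 groups, which are too few for a share under 0.05, 1 gave as many called genes in the LPS comparison of control mice (real 4306, highest other 0), 1 in that of succinate mice (4331, highest other 0) and 1 between the LPS groups (9, highest other 0). For lists called by camera the real number was 6 without LPS (7 of the 10 splits as many; highest other 10) and 10 with LPS (5 of the 10; highest other 15). For genes at an unadjusted p under 0.05 the real number between the LPS groups was 1680 (highest other 1450). Without LPS it was 535 (7 of the 10 splits as many, highest other 2134). The split with 2134 set control replicate 1 with succinate replicates 1 and 2 against the rest, which points to a structure of the samples other than succinate. The replicate numbers were taken to pair these samples, though shared library classes could account for part of that likeness. The 3 other splits that part all 3 pairs gave 621, 159 and 312. Of these 3, 1 was as large as the real one. The 6 splits that keep a pair together gave 327 to 2134. For the interaction, 47 of 100 regroupings gave as many genes as the real 560 (highest 2417), and 10 of the 38 that part the pairs did, so chance cannot be excluded.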

How the results depend on the processing

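The class covariate, the fit within 1 class and the GC and length offset were chosen only after the results were seen. The other settings were planned.

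Both LPS responses kept their counts within 1.5 times in all settings but 1. Within the 7 libraries of 1 class 1211 genes rose and 887 fell in control mice, and 1143 and 1077 in succinate mice, where fewer libraries were tested. With 1 library left out the counts ranged from 1801 to 2308 up and 1533 to 2239 down in control mice, and from 1626 to 2173 and 1748 to 2283 in succinate mice. Hif1a lost its call in control mice in 12 of 23 settings.

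The succinate comparisons moved much more, and the cause was not tested except where a setting's construction gives it. Without LPS no filter called 34 up and 38 down and DESeq2 1 up, and no left-out library gave a call. With LPS, where 0 were up and 9 down, the counts up were 121 with no filter, 23 with DESeq2, 19 with the class covariate, 1 within 1 class and 1 with the GC and length offset. The counts down were 573 with no filter, 30 with the stricter filter, 317 with DESeq2, 34 with limma-voom, 171 with the class covariate and 35 with the GC and length offset, but 0 with library size only, 0 with only the 2 groups compared and 0 within 1 class. Of the 694 genes called with no filter, 663 were among those tested as reported. With 1 library left out the counts ranged from 0 to 16 up and from 0 to 181 down. Down, 0 were called without control unstimulated 3, control LPS 1 or 2, or succinate LPS 1 or 2, and 3 without control unstimulated 1 or 2. There were 24 without succinate unstimulated 1, 27 without succinate unstimulated 3, 73 without control LPS 3 and 181 without succinate LPS 3. Up, 1 was called without succinate unstimulated 1, 6 without control LPS 3 and 16 without succinate LPS 3. For the interaction no filter called 22 up and 49 down and DESeq2 3 down, and other settings 0.

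With the replicate block the LPS groups differed in 5 genes up and 72 down. Their numbers did not pair them (correlations -0.03 to 0.09, 1 of 3 best with its own number), so this is a hint at most. The replicate block also called ribosomal proteins in the LPS response of succinate mice (adjusted p = 0.0286) and cholesterol synthesis (0.0419) and Ly6C-high markers (0.0449) between the LPS groups, and ended the interaction calls of antigen presentation (0.0526) and TLR4 components (0.0523). Without LPS, where the numbers were taken to pair the samples, it ended the call of macrophage markers and no other.

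The direction of the camera test, which follows all members and can differ in sign from the median, turned with a call in either setting only without LPS, where of the lists concerned only the respiratory chain was called as reported. Within 1 class the medians were 0.17 for interferon-stimulated genes, 0.27 for feedback regulators and 0.14 for TLR4 components, from 1 library per group. The respiratory chain was at 0.03 without succinate unstimulated 2 (range -0.25 to 0.03). Ribosomal proteins were at -0.09 without control unstimulated 2 and -0.12 without succinate unstimulated 1 (range -0.12 to 0.14). NRF2 targets were at 0.23 without succinate unstimulated 3 (range -0.13 to 0.26). The cause was not tested. Called in every setting between the LPS groups were the interferon, feedback, ribosomal, NRF2 and B-cell lists, with the preset correlation. By contrast fry called 0 of 30 lists there and 0 between the unstimulated groups, against 11 in each LPS response.

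With library size only, the share of higher genes among those at an unadjusted p under 0.05 between the LPS groups was 69.7% in place of 30.2%, and the medians of 8 lists there changed sign, of which only TLR4 components were called (the others were cytokines, glycolysis, inflammasome, chemokine receptors, stress response, macrophages and dendritic cells). So did medians near 0 in the other comparisons, none of them called. Not run were the alternatives for normalised units. Depth limits genes near the floor, such as Sucnr1, whose changes were not detectable at this depth.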

Other observations

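The tests on the 9 genes, the comparison with other cell types and the permutation of list scores were chosen only after the results were seen. The test on B-lineage genes was set before its result was seen.

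Few transcripts of the succinate receptor were found in any group: Sucnr1 had 2 counts in all, both in 1 library of succinate mice with LPS. Slc13a3, which carries dicarboxylates such as succinate into cells, had 3 to 14 counts per library and passed in none of the comparisons (LPS in succinate mice -1.08, adjusted p = 0.159). The glycolytic gene Gapdh had 166 to 1705 counts per library, low for a gene of its usual abundance, and its variation did not follow the groups: control unstimulated 1, succinate unstimulated 2 and control LPS 3 had 1203, 1140 and 1705, and the other 9 had 166 to 331. How reads shared with its many pseudogenes were counted is not known here.

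B-lineage transcripts beyond the fixed list also lay higher in succinate mice. Of 21 such genes, written down before the test, 18 were measured, and 15 were higher without LPS and 14 with LPS. The B-cell transcription factor gene Spib was at 5.43 against 2.94 CPM without LPS and 10.5 against 7.03 with it, its co-activator Pou2af1 at 2.82 against 1.83 and 4.56 against 2.64, the J chain gene Jchain at 13.4 against 8.97 and 23.8 against 15.2, and Ighd at 3.05 against 1.37 and 3.02 against 2.16 (group means, n = 3). Lower without LPS were Bank1 (log2 fold change -0.22), Cd38 (-0.09) and Bach2 (-0.40), and lower with it were Bank1 (-0.02), Cd38 (-0.35), Blnk (-0.31) and Dntt (-0.82).

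A hypothesis is that slightly more B-lineage cells were among the sorted monocytes of succinate mice. Its test, a median of B-lineage genes outside the list above 0.30 in both comparisons, gave 0.39 without LPS and 0.45 with LPS. Most of these genes lay at 2.94 CPM or less in unstimulated control cells. Those above that level were, without LPS, at 0.58 (Jchain), 0.18 (Igkc), 0.07 (Ralgps2), 0.06 (Blnk) and -0.40 (Bach2). The median without LPS thus rested largely on genes with few counts. A lower share of monocytes, which would raise all other cell types alike, stays open. Among types with low baseline markers the largest shortfall against B cells, that of dendritic cells, was 2.08 SE in the smaller of both comparisons (bound 2.78 for 3 against 3 libraries, put in place of 2 after the value was seen). Without and with LPS, medians were 0.19 and -0.04 for dendritic cells and -0.07 and 0.64 for erythroid cells. Those of eosinophils, basophils and mast cells rose in both (0.22 and 0.49). T and NK cell markers had too few measured members for this comparison. Of them, Nkg7 (0.52) and Lck (0.97) rose with LPS adjusted over their list alone, and no other member passed. The CD11b and Ly6C gate should remove B cells. In cells of succinate mice Ighm was at 177 CPM without LPS, and Igkc at 47.0 CPM without and 86.4 CPM with LPS. Transcription of these genes within monocytes or progenitors was not tested and stays open, as does chance.

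The 9 genes lower in LPS-treated monocytes of succinate mice had a median of -0.81 and a median SE of 0.12. With library size alone their median was -0.69, and the calls ended because the adjusted p-values rose to between 0.0976 and 0.121. That switch moved all genes by a near-constant amount (median of all genes -0.014 to 0.107). It could not undo changes of -1.36 to -0.72, so it shows only that the choice between these 2 scalings is not the whole cause. Other errors of scaling were not tested. Library class and GC content or gene length were likewise weighed only as the whole cause. With the library class as a covariate their median was -0.81, and within 1 class, with fewer libraries, it was -0.83. Of the LPS libraries, the fit within 1 class left out only control LPS 3. The 9 genes were selected for a difference over all LPS libraries, which a class effect on that library alone would seldom give. These values thus cannot decide on the library class. GC content or gene length is argued against by -0.77 with these trends removed, where 8 of the 9 were still called. That succinate in the diet may lower these genes after LPS is a hypothesis found and tested on the same libraries, and with 3 libraries per group the 10 possible splits cannot give a share under 0.05.

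List scores per library were compared between succinate and control mice by an exact permutation within the unstimulated and the LPS libraries (400 splits, 2-sided, smallest possible p = 0.005). Of 30 lists none passed the adjustment. A single list at the smallest possible p can reach only an adjusted p of 0.15, or 0.375 in the paired version below. Failing the adjustment was thus nearly fixed by the design and does not weigh against a list. B-cell markers gave a mean difference of 0.55 log2 units (exact p = 0.005, adjusted p = 0.15), Ly6C-low markers -0.22 (exact p = 0.01, adjusted p = 0.15), phagocyte genes -0.20 (exact p = 0.03, adjusted p = 0.3) and interferon-stimulated genes -0.31 (exact p = 0.095, adjusted p = 0.407). With the unstimulated libraries exchanged only within their pairs (160 splits, smallest possible p = 0.0125) none passed either, with B-cell markers at an exact p of 0.0125 (adjusted p = 0.375) and Ly6C-low markers at 0.025 (adjusted p = 0.375). The 3 differences within pairs had 1 sign for 9 of the 30 lists, where 7.5 would by chance, among them the B-cell (higher), Ly6C-high, Ly6C-low, phagocyte and macrophage lists (lower).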
